A study of Mus musculus with 29 samples.

How the data were processed

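The 29 samples are total RNA of J774.A1 cells, untreated or given latex beads coated with avidin, Fc fragment, LPS or mannan at 0.01% for 30 or 60 min in serum-free medium. Groups and replicate numbers came from the sample titles. The labels do not say that replicates were separate cultures, and the design text speaks of triplicates where the treatment protocol speaks of duplicates, so p-values measure only the spread between these samples, which may be technical. Mannan beads at 60 min have replicates 1 and 3, and a replicate 2 was not analysed here.

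Per the labels, the authors hybridised biotin-labelled RNA to CodeLink Mouse Whole Genome bioarrays and read them with the CodeLink EXP software. The deposited scanner files hold, per spot, a mean intensity, a local background intensity and quality flags. Per the file headers 2 arrays, LPS and mannan replicate 1 at 60 min, were processed on a later day than the others. The deposited value table matched the scanner software's normalized intensity, the background-subtracted intensity divided by 1 constant per array, on a linear scale with no centring of genes (35587 spots matched, largest difference 5e-08). Column medians were 0.989 to 0.996. The columns of the 3 untreated arrays at 30 min hold each other's values, which leaves the group unchanged.

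From the scanner files, spot means were corrected for local background with normexp (offset 50), quantile normalized between arrays and taken to log2. Control spots (320 negative, 300 positive) were left out after the correction, and masked or irregular spots, 0.444% of tested values, were set missing. A probe was tested if it carried the good flag on at least 2 arrays, which left 22366 features, 10555 of them with a gene symbol. Of the 34967 target probes, 15533 carry a RefSeq mRNA accession, and 14763 were given 1 symbol through the reference gene table, 0 several and 20204 none, for 13971 genes. For the 759 genes with more than 1 probe the probe with the highest mean stood for the gene. A probe counted as above background on an array if the software had not marked it as low or masked. Where all arrays of a group lay below background, the fold is a bound, "at least N-fold", from the brighter group's mean against the dimmer group's mean of the higher, per array, of the lowest signal among probes with the good flag and the probe's own signal. The median background was 55 to 63 units per array and the median subtracted signal 55.3 to 91.5.

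Tests used limma (lmFit and eBayes, two-sided) on 10 group means with slide series, read from the titles, as a fixed block (17 residual and 5.11 prior degrees of freedom). Series 1 holds the untreated, Fc and avidin arrays at 30 min and LPS replicate 1 at 30 min. Series 2 holds Fc replicates 1 and 2, LPS and mannan at 60 min. Series 3 holds the other LPS arrays and mannan at 30 min, and untreated, avidin and Fc replicate 3 at 60 min. Contrasts between series therefore rest on LPS replicate 1 at 30 min and Fc replicate 3 at 60 min. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 within each of 24 comparisons. These were 8 of beads with untreated cells, 12 between beads, and 4 of the change in response from 30 to 60 min. Gene lists, 19 with 545 genes of which 428 had a tested probe, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a comparison. Fry tests whether the genes of a list move on balance 1 way, and does not compare them with other genes. Of 86 called shifts 22 held with an estimated correlation and 47 with fry. The change of untreated cells over time was added after the data were seen. The design, lists, alternatives and naming rule were fixed before the data were examined.

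The rule named, for each bead type against untreated cells, the 8 largest rises and 4 largest falls among called genes (the 3 smallest p where none was called), and for each pair of bead types the 4 largest in each direction. It added Tnf, Cxcl2, Il1b, Nfkbia, Ptgs2, Egr1 and Fos throughout and up to 4 members of each list with the smallest p. A few genes that the rule named are not reported here. Alternatives were other scalings and background settings, other filters, all probes, other treatments of slide series, a replicate block, eBayes with trend and robust on, 1 slide series alone, and each array left out in turn. Others, chosen after seeing the data, are named with their results.

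On simulated data of 20747 genes, Fc against untreated at 30 min recovered 80.6%, 97.0% and 100% of genes changed 1.5, 2 and 4-fold, with 4.15% false calls. LPS against untreated at 60 min recovered 11.9%, 68.7% and 97.0% (4.84% false), LPS against Fc at 60 min 77.6%, 98.5% and 100% (6.12% false), and the LPS response over time 1.49%, 46.3% and 90.9% (8.91% false). A chemokine shift of 0.3 set for Fc at 30 min was found as 0.275, with 0 of 18 other lists called. Real arrays may give other rates.

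Versions were R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays and the signal over background limit the precision.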

Results

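Gene expression was measured in J774.A1 cells, a mouse macrophage-like line used to study the engulfment of particles. Cells stayed untreated or took up latex beads, 1 µm across, that carried avidin, the Fc fragment of mouse IgG, lipopolysaccharide (LPS) from Klebsiella pneumoniae or mannan from Saccharomyces cerevisiae. Fc fragments bind Fc-gamma receptors and LPS is sensed through Toll-like receptor 4. Mannan is bound by mannose-recognising lectins, and avidin is a biotin-binding protein of egg white. RNA was taken after 30 or 60 min, and each sample was read on 1 CodeLink bioarray, a 1-colour array. The 29 arrays form 10 groups of 3, except mannan at 60 min, which has 2. Between 16898 and 20742 of the 34967 probes per array, or 48.3 to 59.3%, carried the scanner software's good flag. The design asks how the receptor a particle engages shapes the cell's transcriptional response.

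Values are log2 changes from limma with the slide series as a block, followed by ± their standard error (SE). Adjusted p-values are Benjamini-Hochberg values over the probes of 1 comparison, and levels are means of normalized log2 intensity ± SD. The arrays came from 3 slide series that were unevenly spread over the groups. Reduced fits left out 1 array each.

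Across the 8 comparisons of beads with untreated cells, the chemokine Cxcl2, which attracts neutrophils, rose in 8 of 8, with and without the slide series in the model. The 4 comparisons of 1 time share their 3 untreated arrays. Zfp36, whose protein destabilises cytokine mRNAs, rose in 7 of 8 with the block and 8 without it. Plk2, a kinase induced by growth signals, and Egr2, an immediate early transcription factor, each rose in 5 of 8, and in 7 and 6 of 8 without the block. Tnf, the inflammatory cytokine, rose in 4 of 8 and the chemokine Ccl3 in 4 of 8, against 5 and 7 without the block. The AP-1 subunit Fos and the NF-kB inhibitor Nfkbia did not pass in any of the 8 with either model. Il1b, another inflammatory cytokine, passed in 1 of 8, and that without the block. Egr1, also an immediate early transcription factor, lay above background on 0 of 29 arrays and was not tested.

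**Figure D1:**
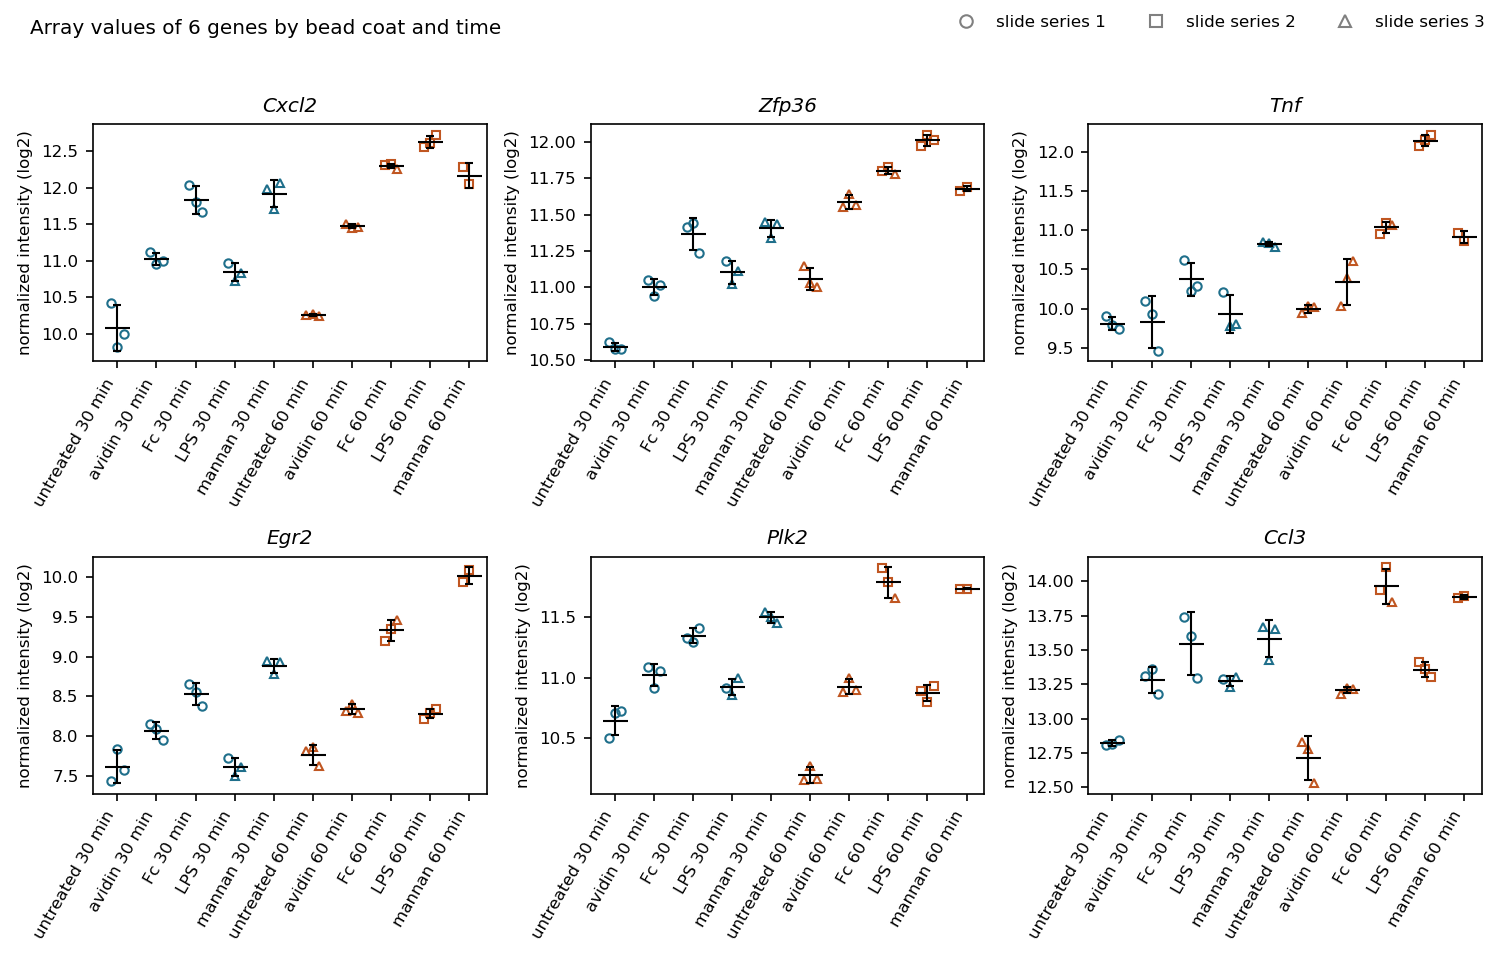
Normalized log2 intensity (vertical axis, before any correction for slide series) of Cxcl2, Zfp36, Tnf, Egr2, Plk2 and Ccl3 on each array, by group, where each point is 1 array, its shape the slide series and each bar the group mean ± SD. Tnf averaged 12.14 ± 0.07 (SD, n = 3) with LPS beads at 60 min against 9.99 ± 0.05 (SD, n = 3) in untreated cells.

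Fc-coated beads against untreated cells at 30 min addressed the early response to opsonised particles. Cxcl2 rose by 1.76 ± 0.12 (adjusted p = 2.3e-08), from 10.08 ± 0.31 to 11.84 ± 0.19 (SD, n = 3 each). Ccl7, which attracts monocytes, rose by 1.05 ± 0.16 (adjusted p = 0.00032), and Csf2, the growth factor GM-CSF, by 1.00 ± 0.11 (adjusted p = 2.6e-05). Egr2 rose by 0.91 ± 0.10 (adjusted p = 2.0e-05). Hnrnpu, an RNA-binding protein of the nuclear matrix, fell by 1.92 ± 0.28 (adjusted p = 0.00027), and Gja1, the gap junction protein connexin 43, by 1.91 ± 0.31 (adjusted p = 0.00057). Ppp3r1, the regulatory subunit of calcineurin, fell by 1.81 ± 0.26 (adjusted p = 0.00026). In all, 1548 of 22296 probes passed, 558 higher and 990 lower, of which 1003 are named. With the deposited value table the split was 116 higher and 627 lower.

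Other large rises were those of Arl16, a small GTPase, at 0.90 ± 0.13 (adjusted p = 0.00027), and of Sbk1 and Ilk, integrin-linked kinase. The last 2 varied between replicates, with SDs of 1.02 for Sbk1 and 0.93 for Ilk among the Fc arrays. Thrap3, a cofactor of transcription and splicing, had a log2 change of −1.71 ± 0.20 (adjusted p = 3.8e-05). A second Thrap3 probe gave −0.27 ± 0.11 (adjusted p = 0.17). Tnf rose by 0.57 ± 0.14 (adjusted p = 0.012), whereas Il1b (0.30 ± 0.13, adjusted p = 0.16), Fos (0.22 ± 0.18, adjusted p = 0.54), Nfkbia (−0.14 ± 0.10, adjusted p = 0.505) and the prostaglandin synthase Ptgs2 (0.14 ± 0.12, adjusted p = 0.56) did not pass.

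Among the gene groups, 6 of 14 chemokines rose and 0 fell, or 9 adjusted over the list alone, with a median log2 change of 0.34 (camera adjusted p = 1.2e-09, and adjusted p = 0.012 with an estimated correlation). Ccl3 rose by 0.72 ± 0.10 and Ccl2, which recruits monocytes, by 0.72 ± 0.10. Of 36 genes of actin and the phagocytic cup, 12 fell and 1 rose, or 15 and 2 adjusted over the list alone, with a median of −0.15 (adjusted p = 1.3e-05, but adjusted p = 0.13 with an estimated correlation). Among them the actin-nucleating subunit Actr2 fell by 1.00 ± 0.15, the adhesion protein vinculin (Vcl) by 1.10 ± 0.17 and the Rac activator Vav3 had a change of −1.15. Of 58 phagosome and lysosome genes 8 fell and 1 rose, or 13 and 3 adjusted over the list alone, with a median of −0.06 (adjusted p = 0.020, but adjusted p = 0.21 with an estimated correlation). The proton pump subunit Atp6v1a fell by 1.42 ± 0.27 and the fusion protein Vamp3 by 0.65 ± 0.12. Cholesterol genes had a median of −0.16 with 3 of 26 lower, or 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.0056, but adjusted p = 0.10 with an estimated correlation). Sqle, an enzyme of sterol synthesis, fell by 0.92 ± 0.17 and the efflux pump Abca1 by 0.66 ± 0.14. Proliferation genes had a median of −0.06 with 3 of 28 lower and 1 higher, or 6 and 1 adjusted over the list alone (adjusted p = 0.032, but adjusted p = 0.43 with an estimated correlation).

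Of 26 immediate early genes 3 rose and 2 fell, or 5 and 3 adjusted over the list alone (adjusted p = 0.25), with Plk2 and Ier3, an early gene of the stress response, at 0.70 each and the TGF-beta-induced Klf10 at −0.67. Of 37 NF-kB targets 3 rose and 1 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.22), with Zfp36 at 0.77 ± 0.07. Of 23 heat shock and unfolded protein genes 3 rose and 5 fell, or 4 and 8 adjusted over the list alone (adjusted p = 0.11). Of these, Ppp1r15a, which restores translation after stress, rose by 0.81 and the mitochondrial chaperone Hspd1 had a change of −0.94. Of 28 interferon response genes 2 rose and 3 fell, or 3 and 6 adjusted over the list alone (adjusted p = 0.15). Of 18 MAPK feedback genes 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (adjusted p = 0.39). In 12 oxidative burst genes 3 fell and 0 rose, or 4 and 1 adjusted over the list alone (adjusted p = 0.25), among them the oxidase subunit Ncf1, which fell by 1.13 ± 0.18. Of 30 phagocytic and pattern receptors 2 rose and 2 fell, or 4 and 3 adjusted over the list alone (adjusted p = 0.47), with the LPS receptor Tlr4 at −0.50 and its partner Ly96 at 0.50.

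All 6 arrays of this comparison came from 1 slide series, and fitted alone they gave 804 probes (248 higher, 556 lower). Adjusted p was then 0.0031 for Cxcl2, 0.080 for Tnf and 0.15 and 0.19 for Sbk1 and Ilk. Fits of 1 series largely keep the changes by construction and retest only their spread. The list shifts had adjusted p of 8.6e-08 for chemokines, 4.5e-05 for actin, 0.030 for phagosome, 0.0088 for cholesterol and 0.062 for proliferation genes. The count was 671 without untreated replicate 2, 835 without untreated replicate 3 and 774 without Fc replicate 2. Of 6 reduced fits the calls were kept in 3 for Tnf (adjusted p = 0.075 without Fc replicate 1), 4 and 3 for Sbk1 and Ilk (adjusted p = 0.077 and 0.082 without untreated replicate 3) and 3 each for the phagosome and proliferation shifts (adjusted p = 0.14 and 0.17 without untreated replicate 2).

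LPS-coated beads at 30 min raised Cxcl2 by 0.89 ± 0.17 (adjusted p = 0.026), from 10.08 ± 0.31 to 10.85 ± 0.12 (SD, n = 3 each). Zfp36 rose by 0.59 ± 0.10 (adjusted p = 0.012). Arl16 rose by 1.05 ± 0.19, the transglutaminase Tgm5 by 0.93 ± 0.18, Usp29 by 0.82 ± 0.14, Cmbl by 0.64 ± 0.12 and Pcnx4 by 0.56 ± 0.12. Ppp3r1 fell by 1.96 ± 0.37 (adjusted p = 0.022), the thioesterase Lypla1 by 1.47 ± 0.30 (adjusted p = 0.038) and the first Thrap3 probe by 1.44 ± 0.28 (adjusted p = 0.026). The second gave −0.26 ± 0.16 (adjusted p = 0.63). Tnf (0.40 ± 0.19, adjusted p = 0.48), Il1b (0.13 ± 0.18, adjusted p = 0.88), Fos (0.26 ± 0.25, adjusted p = 0.80), Nfkbia (0.17 ± 0.15, adjusted p = 0.77) and Ptgs2 (−0.34 ± 0.17, adjusted p = 0.525) did not pass.

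The count was 62 probes, 20 higher and 42 lower, with 32 named. With the deposited table the split was 3 higher and 27 lower. Of 14 chemokines 1 rose, or 4 adjusted over the list alone, with a median of 0.32 (adjusted p = 1.7e-06, but adjusted p = 0.063 with an estimated correlation). The interferon group had a median of −0.16 with 0 of 28 members past limma's threshold, 1 up and 4 down at an unadjusted p under 0.05, and 1 up and 1 down adjusted over the list alone (adjusted p = 0.020, but adjusted p = 0.31 with an estimated correlation and 0.38 without the slide series). Of 26 immediate early genes 1 fell, or 2 rose and 2 fell adjusted over the list alone: Gadd45b, a stress-induced growth arrest gene, fell by 0.71 ± 0.13. Of the LPS arrays replicate 1 shared a slide series with the untreated ones. That series alone gave 6 probes, with adjusted p of 0.26 for Cxcl2 and 0.16 for Zfp36. Its shifts had adjusted p of 7.7e-06 for chemokines and 0.018 for interferon genes. Wnt8a, which fell by 1.83, and Olfr432, at least 1.10-fold higher, had adjusted p of 0.16 and 0.23 without the block, where 605 probes passed. The count was 159, 8 and 15 without untreated replicates 1, 2 and 3. Of the 12 largest changes only Zfp36 and Wnt8a held in all 5 reduced fits, which kept LPS replicate 1. Cxcl2 and Thrap3 held in 3 and the interferon shift in 4 (adjusted p = 0.11, 0.11 and 0.093 without untreated replicate 2).

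Avidin-coated beads at 30 min raised Cxcl2 by 0.94 ± 0.12 (adjusted p = 0.0021), from 10.08 ± 0.31 to 11.03 ± 0.08 (SD, n = 3 each). Csf2 rose by 0.64 ± 0.11 (adjusted p = 0.043) and Zfp36 by 0.41 ± 0.07 (adjusted p = 0.034). Cybb, the catalytic subunit of the phagocyte oxidase, fell by 2.02 ± 0.37 (adjusted p = 0.046), the transcription factor Runx1 by 0.51 ± 0.08 (adjusted p = 0.034) and Gatd3a by 0.44 ± 0.08 (adjusted p = 0.043). Plk2 (0.38), Egr2 (0.45), Ccl7 (0.80) and Ccl3 (0.46) had an adjusted p of 0.062 each. Tnf (0.02 ± 0.14, adjusted p = 0.97), Il1b (0.18, adjusted p = 0.555), Fos (−0.14, adjusted p = 0.80), Nfkbia (−0.22, adjusted p = 0.32) and Ptgs2 (0.13, adjusted p = 0.70) did not pass. The count was 7 probes, 3 higher and 4 lower, 6 of them named. The split was 1 higher and 0 lower with either the 75th percentile scaling or the deposited table, or 2 and 1 with the floored signal.

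Of 14 chemokines 1 rose here, or 7 adjusted over the list alone, with a median of 0.30 (adjusted p = 1.7e-07, and adjusted p = 0.036 with an estimated correlation). Avidin replicate 3 stood apart, averaging 8.92 over the 990 probes lower with Fc beads against 9.21 and 9.30 on replicates 1 and 2. Actin and phagocytic cup genes had a median of −0.17 with 0 of 36 past limma's threshold, 3 up and 15 down at an unadjusted p under 0.05, and 2 up and 11 down adjusted over the list alone (adjusted p = 2.5e-05, but adjusted p = 0.11 with an estimated correlation). In the next 4 groups 0 members passed in limma. Cholesterol genes had a median of −0.12 with 0 up and 3 down adjusted over the list alone, 0 and 3 at an unadjusted p under 0.05 (adjusted p = 0.0029, but adjusted p = 0.089 with an estimated correlation), and 0.03 with the deposited table. Proliferation genes had a median of −0.12, with 0 up and 6 down adjusted over the list alone, 0 and 8 unadjusted (adjusted p = 0.0020, but adjusted p = 0.20 with an estimated correlation), and likewise 0.03 with the deposited table. Heat shock genes had a median of −0.08, with 2 up and 8 down adjusted over the list alone, 2 and 9 unadjusted (adjusted p = 0.014, but adjusted p = 0.11 with an estimated correlation), though 0.08 with the deposited table and 0.0042 with the 75th percentile scaling. Ribosomal protein genes had a median of 0.09, with 2 up and 0 down adjusted over the list alone, 5 and 0 unadjusted (adjusted p = 0.0029, but adjusted p = 0.20 with an estimated correlation). The interferon group had a median of −0.07 with 0 of 28 past the threshold either way, 1 up and 8 down unadjusted (adjusted p = 0.0165, but adjusted p = 0.205 with an estimated correlation).

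The 6 arrays lay in 1 slide series. A fit of all arrays of that series alone gave 0 probes in limma (3052 at an unadjusted p under 0.05), with adjusted p of 0.211 to 0.215 for the 6 named genes. The shifts had adjusted p of 3.0e-06 for chemokines, 7.1e-05 for actin, 0.0045 for cholesterol, proliferation and ribosomal genes, 0.0053 for heat shock and 0.022 for interferon genes. The count was 56 without the slide series term. It was 351, 1 and 3 without untreated replicates 1, 2 and 3 and 13, 507 and 1 without avidin replicates 1, 2 and 3. Of the 6 genes only Cxcl2 held its call whichever array was left out. The interferon (kept in 4 of 6 reduced fits), heat shock and proliferation shifts ended without avidin replicate 3 (adjusted p = 0.23, 0.051 and 0.051) and the ribosomal one without untreated replicate 2 (adjusted p = 0.084).

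Mannan-coated beads at 30 min raised Cxcl2 by 2.03 ± 0.22 (adjusted p = 5.3e-05), from 10.08 ± 0.31 to 11.92 ± 0.19 (SD, n = 3 each). Egr2 rose by 1.44 ± 0.18 (adjusted p = 0.00039), Tnf by 1.44 ± 0.24 (adjusted p = 0.016) and Csf2 by 1.24 ± 0.20 (adjusted p = 0.0093). Zfp36 rose by 0.93 ± 0.12 (adjusted p = 0.00077) and Plk2 by 0.84 ± 0.14 (adjusted p = 0.0093). Il1b (0.73 ± 0.23, adjusted p = 0.80), Fos (0.73 ± 0.32, adjusted p = 0.84), Nfkbia (0.29 ± 0.19, adjusted p = 0.88) and Ptgs2 (0.52 ± 0.22, adjusted p = 0.82) did not pass. The count was 10 probes, 7 higher and 3 lower, with 7 named. The split was 3 and 6 with the deposited table, which shifted the median of all probes by 0.13, and 5 and 5 with the floored signal.

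Of 14 chemokines 1 rose with mannan, or 7 adjusted over the list alone, with a median of 0.44 (adjusted p = 1.2e-10, and adjusted p = 0.0077 with an estimated correlation). Of 37 NF-kB targets 3 rose, or 4 adjusted over the list alone, with a median of 0.11 (adjusted p = 4.9e-05, and adjusted p = 0.0495 with an estimated correlation). Of 26 immediate early genes 2 rose, or 3 up and 1 down adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0030, but adjusted p = 0.18 with an estimated correlation). The interferon group had a median of −0.15 with 0 of 28 past limma's threshold or over the list alone, 0 up and 4 down at an unadjusted p under 0.05 (adjusted p = 0.029, but adjusted p = 0.29 with an estimated correlation and 0.90, with a median of −0.02, without the slide series). No slide series held both groups, so these changes passed through the linking arrays. Without the block the count was 448. Cxcl2 then changed by 1.84, Egr2 by 1.27, Tnf by 1.02 (adjusted p = 0.00046), Il1b by 0.57 (adjusted p = 0.026) and Ptgs2 by 0.85 (adjusted p = 0.0011). Wnt8a, which fell by 1.82 with the block, changed by −0.06 (adjusted p = 0.93). The 6 rises held in all reduced fits, none without LPS replicate 1. The count was 31 and 23 without LPS replicates 2 and 3 at 30 min, and the interferon shift was kept in 7 of 10 reduced fits (adjusted p = 0.15 without mannan replicate 3).

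At 60 min, Fc-coated beads raised Plk2 by 1.47 ± 0.11 (adjusted p = 1.9e-08) and Egr2 by 1.69 ± 0.14 (adjusted p = 1.7e-07). Cxcl2 rose by 2.0 ± 0.17 (adjusted p = 2.2e-07), from 10.26 ± 0.01 to 12.30 ± 0.03 (SD, n = 3 each). Ccl3 rose by 1.13 ± 0.14 (adjusted p = 8.5e-05) and Ptgs2 by 1.14 ± 0.17 (adjusted p = 0.0016). Ccl7 rose by 1.22 ± 0.22 (adjusted p = 0.012), Tnf by 1.07 ± 0.19 (adjusted p = 0.011) and Zfp36 by 0.72 ± 0.10 (adjusted p = 0.00026). Rises of the chemokine receptor-like Ccrl2 (0.85 ± 0.13), Ccl2 (0.80 ± 0.14), Csf2 (0.79 ± 0.16) and Rasgef1b (0.62 ± 0.13) also passed. Il1b (0.26 ± 0.18, adjusted p = 1), Fos (0.40 ± 0.25, adjusted p = 1) and Nfkbia (0.45 ± 0.15, adjusted p = 0.70) did not. The count was 44 probes, 21 higher and 23 lower, with 28 named. The splits were 14 and 63 with the deposited table and 23 and 63 with the floored signal.

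Of 27 immediate early genes 4 rose with Fc beads at 60 min, or 7 adjusted over the list alone, with a median of 0.23 (adjusted p = 3.4e-11, and adjusted p = 0.0012 with an estimated correlation). Of 37 NF-kB targets 5 rose, or 8 adjusted over the list alone (median 0.15, adjusted p = 1.7e-12, and adjusted p = 0.00095 with an estimated correlation). Of 14 chemokines 4 rose, or 6 adjusted over the list alone (median 0.31, adjusted p = 5.2e-14, and adjusted p = 0.00095 with an estimated correlation). The MAPK feedback group had a median of 0.10 with 0 of 18 past limma's threshold, 4 up at an unadjusted p under 0.05 and 3 up adjusted over the list alone (adjusted p = 0.00017, and adjusted p = 0.025 with an estimated correlation). Among the immediate early genes Ier3 rose by 0.58 and Jun, a subunit of AP-1, by 0.49. In the slide series that holds 1 of the Fc arrays and the 3 untreated ones, the count was 21. Adjusted p was 3.8e-05 for Cxcl2, 8.6e-05 for Egr2 and Plk2, 0.007 for Ccl3, 0.021 for Ptgs2, 0.043 for Zfp36, 0.049 for Tnf and 0.10 to 0.40 for Ccl7, Ccrl2, Ccl2, Csf2 and Rasgef1b. The shifts there had adjusted p of 2.4e-10, 2.3e-11, 1.6e-12 and 0.00084, in the order given. Like all changes here, the largest falls (Dld −3.68, Exosc4 −2.60, Ttc1 −1.81, Ak6 −1.67) and the rises of Cdc23 (at least 1.60-fold) and the dim Zfp874a came from that 1 Fc array, replicate 3. Without the block they had adjusted p of 0.24 to 0.71 and 53 probes passed, 18 of them in both models. Csf2 kept its call in 3 and Rasgef1b in 0 of 5 reduced fits (adjusted p = 0.13 each without untreated replicate 3).

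LPS-coated beads at 60 min raised Tnf by 2.19 ± 0.24 (adjusted p = 2.4e-05), from 9.99 ± 0.05 to 12.14 ± 0.07 (SD, n = 3 each). Cxcl2 rose by 2.32 ± 0.22 (adjusted p = 1.6e-06) and Zfp36 by 0.92 ± 0.12 (adjusted p = 0.00028). Egr2 (0.70 ± 0.18, adjusted p = 0.39), Plk2 (0.49 ± 0.14, adjusted p = 0.58), Ier3 (0.75 ± 0.15, adjusted p = 0.063), Ptgs2 (0.81 ± 0.22, adjusted p = 0.54), Il1b (0.70 ± 0.23, adjusted p = 0.93), Nfkbia (0.67 ± 0.19, adjusted p = 0.61) and Fos (0.45 ± 0.32, adjusted p = 1) did not pass. The count was 25 probes, 9 higher and 16 lower, with 14 named. The splits were 9 and 27 with the deposited table and 6 and 30 with the floored signal. The NF-kB group had a median of 0.27, and 2 of 37 rose, or 10 adjusted over the list alone (adjusted p = 2.9e-15, and adjusted p = 0.00040 with an estimated correlation). Of 14 chemokines 1 rose, or 1 adjusted over the list alone (median 0.21, adjusted p = 6.7e-06, and adjusted p = 0.039 with an estimated correlation). Immediate early genes had a median of 0.11 with 0 of 27 past limma's threshold, 6 up at an unadjusted p under 0.05 and 3 up adjusted over the list alone (adjusted p = 3.5e-05, and adjusted p = 0.039 with an estimated correlation). MAPK feedback genes had a median of 0.12 with 0 of 18 past it, 4 up unadjusted and 2 up adjusted over the list alone (adjusted p = 0.011, but adjusted p = 0.15 with an estimated correlation and 0.056 without the slide series).

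The Thrap3 spot was brighter by 3.87 ± 0.36 (adjusted p = 1.6e-06) with LPS beads at 60 min. The Sf3b5 spot 2 columns away was masked on 7 of 7 arrays of that series and 0 of 22 others. No slide series held both LPS and untreated arrays at 60 min. Without the block 32 probes passed, 4 of them in both models. Tnf then changed by 2.14, Cxcl2 by 2.37 and Zfp36 by 0.95. Dld (−3.65), Exosc4 (−2.63), Ttc1 (−1.96) and Ak6 (−1.72), which passed through Fc replicate 3, then stood between −0.39 and 0.14 (adjusted p = 0.905 to 0.970). Cdc23 and Zfp874a were below background in untreated cells. Tnf, Cxcl2 and Zfp36 held in all reduced fits, none without Fc replicate 3. The count was 16 without Fc replicate 2 at 60 min, and the MAPK shift was kept in 7 of 10 reduced fits (adjusted p = 0.066 without untreated replicate 3).

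Avidin-coated beads at 60 min raised Cxcl2 by 1.22 ± 0.12 (adjusted p = 2.2e-05), from 10.26 ± 0.01 to 11.48 ± 0.03 (SD, n = 3 each). Plk2 rose by 0.73 ± 0.08 (adjusted p = 2.2e-05) and Zfp36 by 0.53 ± 0.07 (adjusted p = 0.00064). Egr2 rose by 0.57 ± 0.10 (adjusted p = 0.019) and Ccl3 by 0.49 ± 0.10 (adjusted p = 0.043). Ccp110, a centriole protein, rose by 0.46 ± 0.09, the cytokine Osm by 0.38 ± 0.07, Jun by 0.36 ± 0.07 and Phlda1 at least 1.47-fold. Frat2, an activator of Wnt signalling, fell by 0.65 ± 0.12 (adjusted p = 0.027). The collagen Col23a1 was at least 1.36-fold lower, and Vmn1r53 was below background with avidin (adjusted p = 0.60 without the block). Tnf (0.35 ± 0.14, adjusted p = 0.58), Ptgs2 (0.51 ± 0.12, adjusted p = 0.13), Fos (0.44 ± 0.18, adjusted p = 0.58), Il1b (0.06 ± 0.13, adjusted p = 0.95) and Nfkbia (−0.07 ± 0.10, adjusted p = 0.92) did not pass. The count was 32 probes, 22 higher and 10 lower, with 17 named, and 14 and 1 with the 75th percentile scaling. Of 27 immediate early genes 3 rose, or 5 adjusted over the list alone (median 0.07, adjusted p = 0.00022, but adjusted p = 0.092 with an estimated correlation). Of 14 chemokines 2 rose, or 3 adjusted over the list alone (median 0.18, adjusted p = 4.8e-05, but adjusted p = 0.092 with an estimated correlation). The 6 arrays shared 1 slide series and fitted alone gave 3 probes. Adjusted p was then 0.00062 for Cxcl2, 0.0078 for Plk2, 0.13 for Zfp36, 0.15 for Egr2 and 0.15 to 0.73 for the others. The shifts had adjusted p of 0.0033 for immediate early genes and 4.0e-05 for chemokines. Of the named calls only those of Cxcl2, Plk2 and Zfp36 held whichever array was left out, against 0 to 3 of 6 reduced fits for the others (highest adjusted p = 0.10 to 0.51). The count was 14 without the slide series term. It was 8, 9 and 10 without untreated replicates 1, 2 and 3, and 6 and 13 without avidin replicates 1 and 2.

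Mannan-coated beads at 60 min, measured on 2 arrays, raised Egr2 by 2.43 ± 0.19 (adjusted p = 5.3e-08), from 7.77 ± 0.13 (SD, n = 3) to 10.01 ± 0.10 (SD, n = 2). Cxcl2 rose by 1.85 ± 0.23 (adjusted p = 8.7e-05), Plk2 by 1.35 ± 0.14 (adjusted p = 6.9e-06), and Ptgs2 by 1.30 ± 0.23 (adjusted p = 0.013). Ccl7 rose by 1.48 ± 0.29 (adjusted p = 0.044), Ccl3 by 1.00 ± 0.18 (adjusted p = 0.022) and Rasgef1b by 0.86 ± 0.17 (adjusted p = 0.044). Tnf (0.96 ± 0.25, adjusted p = 0.395), Zfp36 (0.59 ± 0.13, adjusted p = 0.081), Il1b (0.65 ± 0.24), Fos (−0.22 ± 0.34) and Nfkbia (0.43 ± 0.20), the last 3 with an adjusted p of 1, did not pass. The count was 29 probes, 12 higher and 17 lower, with 18 named. The splits were 6 and 22 with the deposited table and 9 and 26 with the floored signal. Of 14 chemokines 3 rose, or 5 adjusted over the list alone (median 0.26, adjusted p = 2.2e-08, and adjusted p = 0.011 with an estimated correlation). Of 37 NF-kB targets 1 rose, or 5 up and 1 down adjusted over the list alone (median 0.18, adjusted p = 2.7e-07, and adjusted p = 0.011 with an estimated correlation). Of 27 immediate early genes 2 rose, or 3 adjusted over the list alone (median 0.14, adjusted p = 0.0048, but adjusted p = 0.16 with an estimated correlation). Of 18 MAPK feedback genes 0 passed in limma, with 2 up unadjusted and 1 up adjusted over the list alone (median 0.11, adjusted p = 0.0079, but adjusted p = 0.16 with an estimated correlation).

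No slide series held both mannan and untreated arrays at 60 min. Without the block 42 probes passed, 8 of them in both models. Egr2 then changed by 2.25, Cxcl2 by 1.91, Tnf by 0.92 (adjusted p = 0.0051) and the Thrap3 spot (3.74 with the block) by 3.27. Dld (−3.57), Exosc4 (−2.79), Ttc1 (−2.02) and Ak6 (−1.80) then stood between −0.31 and 0.06. Egr2, Cxcl2 and Plk2 held in all reduced fits, none without Fc replicate 3. The count was 19 without Fc replicate 2 at 60 min. Of 10 reduced fits the calls were kept in 9 for Ptgs2 and 4 for Rasgef1b (adjusted p = 0.065 and 0.23 without that array), 2 for Ccl7 (adjusted p = 0.22 without mannan replicate 1) and 6 for Ccl3 (adjusted p = 0.10 without Fc replicate 1 at 60 min). The MAPK shift ended without mannan replicate 3 (adjusted p = 0.054).

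**Figure D2:**
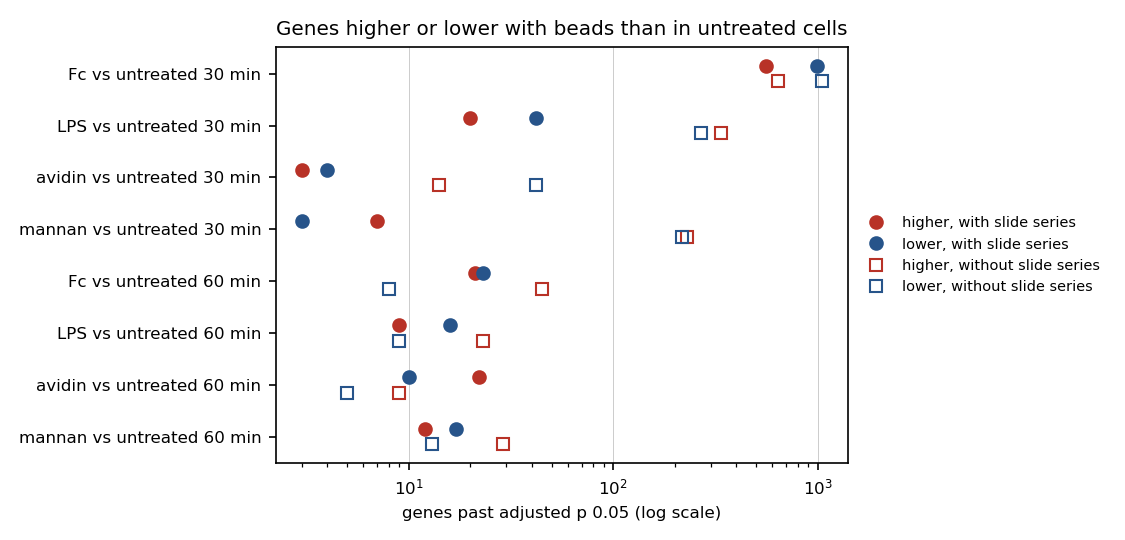
Number of probes past an adjusted p of 0.05 (log axis), higher and lower, in each comparison, with the slide series in the model (filled circles) and without it (open squares). Fc beads at 30 min stand at 558 higher and 990 lower with the term and 641 and 1055 without it.

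With LPS beads at 30 min Egr2 was lower than with mannan beads by −1.33 ± 0.11 (adjusted p = 8.7e-07). Cxcl2 was lower by −1.14 ± 0.14 (adjusted p = 0.0002) and Tnf by −1.03 ± 0.15 (adjusted p = 0.0022), with n = 2 and 3 in 1 series. Ptgs2 was lower by −0.86 ± 0.14 (adjusted p = 0.0046) and Csf2 by −0.67 ± 0.13 (adjusted p = 0.019). Higher with LPS were Tgm5 (0.78 ± 0.15) and Nr2e3, Olfr1508 and Olfr893 (at least 1.24-fold, 1.21-fold and 1.20-fold). In all 54 probes differed, 35 higher and 19 lower with LPS, against 22 and 40 with the deposited table, which shifted the median of all probes by −0.14. Immediate early genes were lower as a group, with 2 of 27 past the threshold, or 9 adjusted over the list alone (median −0.10, adjusted p = 2.0e-07, and adjusted p = 0.020 with an estimated correlation). NF-kB targets were also lower, with 4 of 37, or 7 adjusted over the list alone (median −0.06, adjusted p = 4.4e-05, and adjusted p = 0.031 with an estimated correlation). MAPK feedback (median −0.15), heat shock (−0.07) and cholesterol genes (−0.10) were lower too. In these groups 0 members passed limma's threshold, with 6, 5 and 3 down at an unadjusted p under 0.05, and 4, 3 and 2 down adjusted over the list alone (adjusted p = 0.00040, 0.0016 and 0.0040, and adjusted p = 0.031, 0.031 and 0.045 with an estimated correlation). Chemokines (median −0.13, adjusted p = 0.0040), proliferation (−0.05, adjusted p = 0.023) and granulocyte and dendritic markers (0.17, adjusted p = 0.014) had adjusted p = 0.15, 0.33 and 0.071 with an estimated correlation. The slide series that holds 2 LPS and 3 mannan arrays gave 3 probes. Adjusted p was then 0.00045 for Egr2, 0.0023 for Cxcl2, 0.047 for Tnf and 0.11 for Ptgs2, and up to 0.030 for the 8 shifts. The count was 186 without the block, where the proliferation shift had an adjusted p of 0.090, and 17 without mannan replicate 1. Of these genes only Egr2, Cxcl2 and Tnf held whichever array was left out. Ptgs2 was kept in 5, Csf2 in 3 and the others in 2 of 6 reduced fits (highest adjusted p = 0.11 to 0.24), and the proliferation and granulocyte shifts in 3 of 5 (adjusted p = 0.23 and 0.18 without mannan replicate 2).

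In the other pairs at 30 min, Cxcl2 was higher with Fc than with avidin beads by 0.81 ± 0.12 (adjusted p = 0.024, n = 3 each, and adjusted p = 0.34 in the 6 arrays alone), the 1 probe that passed. Tnf was higher with mannan than with avidin beads by 1.41 ± 0.24 (adjusted p = 0.044, n = 3 each, and 0.99 with adjusted p = 0.0011 without the slide series), among 4 probes, 1 higher and 3 lower. Egr2 was lower with LPS than with Fc beads by a difference of −0.80 ± 0.14 (adjusted p = 0.035, n = 3 each). It was among 6 probes, 2 higher and 4 lower, but only LPS replicate 1 shared the Fc series, where its call ended. The membrane channel Tmem38b was lower with Fc than with mannan beads by a difference of −0.91 ± 0.16 (adjusted p = 0.035), among 6 probes, 3 higher and 3 lower. LPS and avidin beads differed in 3 probes, 1 higher and 2 lower. In 4 of these pairs Wnt8a passed through LPS replicate 1 alone, with changes of −1.75 for LPS against avidin, −1.75 for LPS against Fc, −1.73 for mannan against avidin and 1.74 for Fc against mannan. These were −0.58, −0.58, 0.02 and −0.02 without the block.

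With Fc against avidin beads the chemokines (median 0.17, adjusted p = 0.00086), immediate early genes (0.09, adjusted p = 0.00086) and NF-kB targets (0.06, adjusted p = 0.019) were higher, but with adjusted p = 0.22, 0.22 and 0.30 with an estimated correlation, and with the deposited table, which moved all probes by −0.12, the immediate early and NF-kB medians were −0.0029 and −0.07. With mannan against avidin beads 8 groups were higher: NF-kB targets (0.09, adjusted p = 2.3e-05), immediate early genes (0.19, adjusted p = 6.9e-05), proliferation (0.17, adjusted p = 0.0019), heat shock (0.09, adjusted p = 0.010), actin (0.09, adjusted p = 0.015), chemokines (0.11, adjusted p = 0.015), cholesterol (0.06, adjusted p = 0.031) and MAPK feedback genes (0.10, adjusted p = 0.047), each with an adjusted p of 0.063 or more with an estimated correlation (up to 0.23). With Fc against mannan beads actin (−0.20, adjusted p = 0.0019), proliferation (−0.17, adjusted p = 0.012), NF-kB (−0.15, adjusted p = 0.013), cholesterol (−0.12, adjusted p = 0.016) and heat shock genes (−0.12, adjusted p = 0.025) were lower and granulocyte and dendritic markers higher (0.25, adjusted p = 0.013), with adjusted p between 0.16 and 0.27 with an estimated correlation. With LPS against Fc beads the immediate early genes (−0.07, adjusted p = 0.0027) and chemokines (−0.18, adjusted p = 0.014) were lower and actin genes higher (0.12, adjusted p = 0.0027), with adjusted p of 0.43, 0.46 and 0.46 with an estimated correlation. Fitted within the shared series, the 3 shifts of Fc against avidin had adjusted p of 0.0030, 0.0030 and 0.030, and those of LPS against Fc 0.014, 0.035 and 0.014. Without the block the proliferation shift of Fc against mannan had an adjusted p of 0.081.

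Without the slide series the counts of these 5 pairs were 1 for Fc against avidin, 571 for mannan against avidin, 2393 for Fc against mannan, 6 for LPS against Fc and 0 for LPS against avidin (2099 at an unadjusted p under 0.05 in limma). The splits with the deposited table were 0 and 1, 0 and 6, 6 and 2 (with all probes moved by −0.15), 2 and 13, and 1 and 19, in that order. With the floored signal they were 0 and 5 for mannan against avidin, 4 and 1 for Fc against mannan, 2 and 8 for LPS against Fc and 2 and 12 for LPS against avidin, and 2 and 3 for mannan against avidin with the 75th percentile scaling. Fc against avidin gave 0 probes in limma without Fc replicate 1 or 2 or avidin replicate 1 or 2 (1780 to 2010 unadjusted), 26 without Fc replicate 3 and 15 without avidin replicate 3. Mannan against avidin gave 25 and 11 without LPS replicates 2 and 3 and 2 without avidin replicate 2. Fc against mannan gave 31, 12 and 3 without LPS replicates 2 and 3 and Fc replicate 3, and LPS against avidin gave 5 without avidin replicate 1. Reduced fits kept Cxcl2 in 2 of 6 and Egr2 in 3 of 5 (adjusted p = 0.20 each without Fc replicate 1), and Tnf in 4 and Tmem38b in 5 of 11 (adjusted p = 0.12 and 0.11 without mannan replicate 1). For Fc against avidin the NF-kB shift was kept in 3 of 6 (adjusted p = 0.31 without avidin replicate 3) and the chemokine shift ended without Fc replicate 1 (adjusted p = 0.059). For LPS against Fc the chemokine and actin shifts ended without Fc replicates 1 and 2 (adjusted p = 0.20 and 0.078). For mannan against avidin the MAPK and cholesterol shifts were kept in 5 of 10 (adjusted p = 0.22 and 0.094 without avidin replicate 3) and the actin and heat shock shifts in 8 and 9 (adjusted p = 0.18 and 0.070 without LPS replicate 2). For Fc against mannan the heat shock shift was kept in 8 of 10 (adjusted p = 0.11 without LPS replicate 2), and the cholesterol, proliferation and granulocyte shifts ended without mannan replicate 2 (adjusted p = 0.054, 0.054 and 0.059).

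At 60 min Tnf was higher with LPS than with Fc beads by 1.12 ± 0.15 (adjusted p = 0.00049, n = 3 and 2, as Fc replicate 3 went into the block). Egr2 was lower by −0.99 ± 0.11 (adjusted p = 3.5e-05), Plk2 by −0.98 ± 0.08 (adjusted p = 5.7e-07) and Ccl3 by −0.66 ± 0.11 (adjusted p = 0.0073). Hlx, a homeobox factor, was lower by −0.54 ± 0.11. The stress gene Ddit4 (0.64 ± 0.12, n = 2 with Fc) and Sfr1 (0.61 ± 0.12) were higher, with adjusted p of 0.59 and 0.18 without the block. In all 34 probes differed, 11 higher and 23 lower with LPS, against 14 and 9 with the deposited table and 13 and 15 with the floored signal. NF-kB targets were higher as a group with 1 of 37 past the threshold, or 2 adjusted over the list alone (median 0.08, adjusted p = 0.030, but adjusted p = 0.38 with an estimated correlation, and 3 of 5 reduced fits, with adjusted p = 0.31 without LPS replicate 2). In the series that holds 2 Fc and 3 LPS arrays 5 probes passed, with adjusted p of 0.0038 for Tnf, 0.0087 for Egr2, 0.0061 for Plk2 and 0.092 for Ccl3, and 0.036 for the NF-kB shift. Without the block 15 probes differed. The count was 10 and 9 without Fc replicates 2 and 3 and 18 and 20 without LPS replicates 2 and 3. Tnf, Egr2 and Plk2 held whichever array was left out, while Ccl3 ended without Fc replicate 2 (adjusted p = 0.29). Hlx and Sfr1 kept their call in 0 and Ddit4 in 1 of 6 reduced fits (highest adjusted p = 0.36, 0.43 and 0.91).

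LPS and mannan beads at 60 min differed in Tnf, Egr2 and Plk2. Tnf was higher with LPS by 1.23 ± 0.15 (adjusted p = 0.00034, n = 3 and 2), Egr2 lower by a difference of −1.73 ± 0.11 (adjusted p = 4.7e-09) and Plk2 lower by −0.86 ± 0.08 (adjusted p = 8.7e-06). The niacin receptor Hcar2 (−0.71 ± 0.12) and Gpr176 (−0.60 ± 0.10) were lower too. With 1 unnamed probe these made 6, 1 higher and 5 lower, against 1 and 2 with the deposited table. NF-kB targets were higher, with 1 of 37 past the threshold, or 5 up and 1 down adjusted over the list alone (median 0.09, adjusted p = 0.00017, but adjusted p = 0.086 with an estimated correlation). Heat shock genes were lower, with 0 of 23 in limma and 1 down unadjusted (median −0.04, adjusted p = 0.015, but adjusted p = 0.086 with an estimated correlation). All 5 arrays shared a slide series, and fitted alone they gave 3 probes. Adjusted p was then 0.0025 for Tnf, 0.00029 for Egr2, 0.024 for Plk2, 0.83 for Hcar2 and 0.22 for Gpr176, and 0.0023 and 0.081 for the shifts. Tnf, Egr2 and Plk2 held whichever array was left out, but the count was 24 without mannan replicate 1 and 3 without LPS replicate 2 or 3. Of 5 reduced fits the NF-kB shift was kept in 4, the heat shock shift in 3 and Hcar2 in 2 (adjusted p = 0.21, 0.37 and 0.40 without mannan replicate 1), and Gpr176 in 0 (highest adjusted p = 0.28).

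In the remaining pairs at 60 min Egr2 was higher with Fc than with avidin beads by 1.12 ± 0.14 (adjusted p = 0.00014, n = 3 each). It was higher with mannan than with avidin by 1.86 ± 0.19 (adjusted p = 5.0e-06, n = 2 and 3). It was lower with Fc than with mannan by −0.74 ± 0.12 (adjusted p = 0.017, n = 2 each in 1 series). Plk2 was higher with Fc than with avidin by 0.74 ± 0.11 (adjusted p = 0.00094). Differences from avidin here rest on Fc replicate 3. Tnf was higher with LPS than with avidin by 1.84 ± 0.24 (adjusted p = 0.00035, n = 3 each) and Cxcl2 by 1.10 ± 0.22 (adjusted p = 0.047). Anxa8 (1.03 ± 0.20, and adjusted p = 0.081 without the block) was higher with Fc than with avidin, and Sorcs2 (at least 1.72-fold) and Apol9b (0.73 ± 0.13, and adjusted p = 0.25 without the block) with Fc than with mannan. The counts were 35 for Fc against avidin (9 higher, 26 lower), 20 for mannan against avidin (3 higher, 17 lower), 10 for Fc against mannan (4 higher, 6 lower) and 26 for LPS against avidin (9 higher, 17 lower). NF-kB targets were higher with LPS than with avidin, 1 of 37 past the threshold, or 10 adjusted over the list alone (median 0.22, adjusted p = 1.0e-09, and adjusted p = 0.0047 with an estimated correlation). They were also higher with Fc than with avidin, with 0 of 37 in limma, 7 up unadjusted and 5 up adjusted over the list alone (median 0.13, adjusted p = 4.2e-07, and adjusted p = 0.020 with an estimated correlation). With Fc against avidin, immediate early genes (0.15, adjusted p = 0.00057), chemokines (0.13, adjusted p = 2.8e-05) and heat shock genes (0.09, adjusted p = 0.0078) were higher, but with adjusted p = 0.073, 0.059 and 0.059 with an estimated correlation. With mannan against avidin, NF-kB targets (0.15, adjusted p = 0.00098) and chemokines (0.21, adjusted p = 0.0095) were higher, but with adjusted p = 0.21 and 0.49 with an estimated correlation.

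The Thrap3 spot differed by 4.20 for LPS against avidin, 4.08 for mannan against avidin, −4.17 for Fc against mannan and 4.30 for LPS against Fc. The values of Cdc23, Zfp874a, Dld, Exosc4, Ttc1 and Ak6 against avidin passed through Fc replicate 3. Dld stood at −3.36 for Fc, −3.32 for LPS and −3.24 for mannan, which were −1.19, −0.07 and 0.01 without the block. In the series that holds 1 Fc and 3 avidin arrays 22 probes passed, with adjusted p of 0.0048 for Egr2 and 0.036 for Plk2, and adjusted p up to 0.0075 for the 4 shifts. In the series with 2 Fc and 2 mannan arrays Egr2 had an adjusted p of 0.25 and Sorcs2 and Apol9b 0.33 each. The counts without the block were 61, 36, 3 and 54, of which 2, 2, 3 and 3 passed in both models. The splits were 6 and 70 for Fc against avidin and 7 and 30 for LPS against avidin with the deposited table, and 7 and 70 and 6 and 31 with the floored signal. They were 3 and 15 for LPS against avidin and 4 and 3 for Fc against mannan with the 75th percentile scaling. Single arrays moved mannan against avidin to 31 without Fc replicate 1 or mannan replicate 1. They moved Fc against mannan to 27 without either of these and to 6 and 3 without Fc replicates 2 and 3, and LPS against avidin to 16 and 17 without LPS or avidin replicate 2. Cxcl2 kept its call in 1 of 11 reduced fits (adjusted p = 0.17 without Fc replicate 2). For Fc against mannan Egr2 was kept in 2, Apol9b in 1 and Sorcs2 in 3 of 5 (adjusted p = 0.18 and 0.33 without mannan replicate 3 and 1 without Fc replicate 3). The chemokine shift of mannan against avidin was kept in 7 of 9 (adjusted p = 0.090 without Fc replicate 1).

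**Figure D3:**
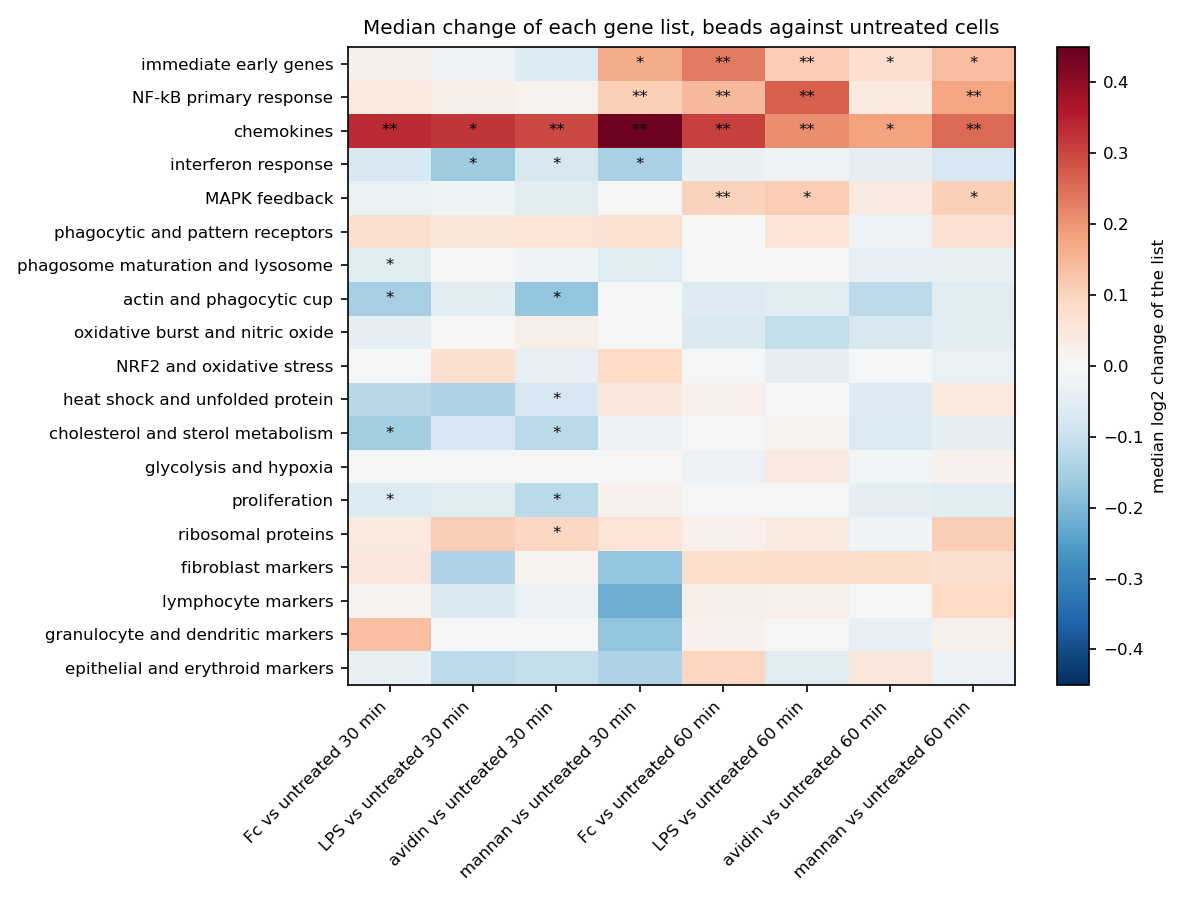
Median log2 change (colour) of each gene list in the 8 comparisons of beads with untreated cells, where a star marks a camera adjusted p under 0.05 with the preset correlation and a pair of stars one that also holds with an estimated correlation. With LPS beads at 60 min the NF-kB list stands at 0.27 and with mannan beads at 30 min the chemokine list at 0.44.

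Whether a response grew between 30 and 60 min was tested as the difference of the 2 changes. The Plk2 response to Fc beads was larger at 60 min by 0.77 ± 0.13 (adjusted p = 0.012, n = 3 each). The Tnf response to LPS beads was larger by 1.78 ± 0.31 (adjusted p = 0.015, n = 3 each) and that of Cxcl2 by 1.43 ± 0.28 (adjusted p = 0.049). For avidin beads 0 probes passed in limma, with 1085 at an unadjusted p under 0.05. The smallest p belonged to Gadd45g (0.61 ± 0.14) and to Col23a1 and Olfr618, each below background in a group (adjusted p = 0.81 each). For mannan beads 11 probes passed, 3 higher and 8 lower. Among the 7 named were Thrap3 (4.46) and Wnt8a (1.63), Dld (−3.08), Exosc4 (−2.63), Ttc1 (−2.60) and Ak6 (−2.21). Wnt8a passed through LPS replicate 1 at 30 min and the last 4 through Fc replicate 3 at 60 min. The counts were 14 for Fc beads (3 higher, 11 lower) and 18 for LPS beads (6 higher, 12 lower), among them Thrap3 at 5.31 and Wnt8a at 1.55 for LPS and Dld at −2.68 for Fc.

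NF-kB targets in the LPS response had a median difference of 0.21, with 1 of 37 past the threshold, or 3 adjusted over the list alone (adjusted p = 5.3e-06, and adjusted p = 0.041 with an estimated correlation). Immediate early genes differed by a median of 0.20 for Fc, 0.22 for LPS and 0.16 for avidin beads (adjusted p = 0.00051, 0.00065 and 2.1e-05, but adjusted p = 0.083, 0.088 and 0.072 with an estimated correlation). MAPK feedback genes differed by 0.20, 0.34 and 0.15 (adjusted p = 0.0010, 0.0016 and 0.0025, but adjusted p = 0.083, 0.088 and 0.11 with an estimated correlation). In the Fc response NF-kB (0.11, adjusted p = 0.0018), actin (0.09, adjusted p = 0.0064), heat shock (0.14, adjusted p = 0.011), phagosome (0.08, adjusted p = 0.035) and cholesterol genes (0.11, adjusted p = 0.041) also shifted, with adjusted p between 0.083 and 0.28 with an estimated correlation. In the avidin response actin genes (0.10, adjusted p = 0.034) and ribosomal protein genes (−0.11, adjusted p = 0.0034) shifted, with adjusted p = 0.42 and 0.31 with an estimated correlation. Without the block the counts were 7 for Fc, 7 for LPS and 11 for mannan, of which 1, 4 and 1 passed in both models. The splits with the deposited table were 1 and 42 for Fc and 4 and 16 for LPS and with the floored signal 3 and 42 and 4 and 19. Plk2 held in all reduced fits, none without Fc replicate 3 at 60 min. Tnf had adjusted p = 0.054 without Fc replicate 1 at 60 min, and Cxcl2 was kept in 2 of 13 (highest adjusted p = 0.13, without replicate 2). The mannan count was 25 without LPS replicate 2 at 30 min. In the Fc response the phagosome and cholesterol shifts were kept in 9 and 8 of 13 (adjusted p = 0.14 and 0.11 without untreated replicate 2 at 30 min). In the avidin response the MAPK and actin shifts were kept in 15 and 10 of 16 (adjusted p = 0.098 and 0.51 without avidin replicate 3 at 30 min) and the ribosomal one in 14 (adjusted p = 0.16 without untreated replicate 2 at 30 min).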

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

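Of the tests in this part, that of the second Thrap3 probe was set before its result was seen, and those of the Sf3b5 spot and of the splits were chosen after. By a test of the difference, the responses at 60 and 30 min differed in 14 probes for Fc, 18 for LPS and 11 for mannan beads. The differences were 0.77 for Plk2 with Fc beads, 1.78 for Tnf and 1.43 for Cxcl2 with LPS beads, and 5.31 and 4.46 for Thrap3 with LPS and mannan beads. For Fc and for LPS, 22 of 100 splits of the arrays gave as many probes (highest other 1053 and 65, real values 14 and 18), so chance is not excluded for either count. For avidin the real value was 0 in limma (1085 at an unadjusted p under 0.05), so 100 of 100 did by construction, which tests nothing (highest other 1453). The cause of the highest counts was not tested.

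The Thrap3 spot averaged 12.66 ± 0.11 (SD, n = 5) on the LPS and mannan arrays at 60 min, 8.41 ± 0.31 (SD, n = 2) on the Fc arrays of the same slide series and 8.92 ± 0.61 (SD, n = 22) on the others. A displaced or overlapping spot is a candidate explanation, since the bright Sf3b5 spot, 2 columns and 1 row away, was masked on 7 of 7 arrays of that series and 0 of 22 others (Fisher's exact test, two-sided, p = 6.4e-07). On those 2 Fc arrays an unnamed spot in the column between them averaged 12.85 ± 0.03 against 8.30 ± 0.15 on the 22 others. A second Thrap3 probe elsewhere on the array differed between LPS and Fc beads at 60 min by 0.073 ± 0.13 (SE, adjusted p = 0.93). That probe lay above background on 4 of these 6 arrays, which keeps a rise of the transcript open.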

How the results depend on the processing

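Of the tests in this part, the processing day as a block, leaving out both later-processed arrays, setting contaminated spots missing, leaving out the spots at the far end of the array and the calls made in both models were chosen after the results were seen. A bead name alone stands for its comparison with untreated cells, a pair of names for the comparison of those beads, and over time for the change from 30 to 60 min. Of 234 gene values and 86 list shifts followed, direction and call were kept by 234 and 85 with all probes tested, by 228 genes with eBayes with trend and robust and by 216 and 85 with the processing day as a block. Fewer calls were kept with the floored signal (187 and 84), the 75th percentile scaling (196 and 74) and the deposited table (160 and 71). Without the slide series 52 genes and 6 lists lost their call, 4 genes gained one and 14 genes and 1 list reversed. In the arrays of 1 series 68 of 139 genes and 2 of 41 lists lost theirs, and with an estimated correlation and fry 64 and 39 of the 86 lists. The signal over background limits the dim probes. For all changes in this part the cause was not tested.

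Counts that moved by over 1.5 times follow. Without the slide series, and then with it as a random block, they were 605 and 640 for LPS, 56 and 56 for avidin, 448 and 536 for mannan, 0 and 0 (limma, 2099 and 2118 unadjusted) for LPS-avidin, 186 and 186 for LPS-mannan, 571 and 629 for mannan-avidin, 2393 and 2510 for Fc-mannan at 30 min, 14 and 14 for avidin, 54 and 76 for LPS-avidin, 15 and 15 for LPS-Fc, 61 and 66 for Fc-avidin, 36 and 41 for mannan-avidin, 3 and 3 for Fc-mannan at 60 min, 7 and 7 for Fc, 7 and 7 for LPS over time. In the arrays of 1 series they were 804 for Fc, 6 for LPS, 0 (limma, 3052 unadjusted) for avidin, 3 for LPS-Fc, 0 (limma, 1655 unadjusted) for Fc-avidin and 3 for LPS-mannan at 30 min and 21 for Fc, 3 for avidin, 22 for Fc-avidin, 5 for LPS-Fc, 3 for LPS-mannan and 2 for Fc-mannan at 60 min. Called in both models were 0 (limma) for LPS-avidin, 2 for LPS-Fc, 2 for mannan-avidin and 3 for Fc-mannan at 30 min, 18 for Fc, 4 for LPS, 14 for avidin, 8 for mannan, 3 for LPS-avidin, 11 for LPS-Fc, 2 for Fc-avidin, 2 for mannan-avidin and 3 for Fc-mannan at 60 min and 1 for Fc, 4 for LPS and 1 for mannan over time. With the 75th percentile scaling they were 1 for avidin, 33 for LPS-mannan and 0 (limma, 1779 unadjusted) for Fc-avidin at 30 min, 15 for avidin and 22 for Fc-avidin at 60 min and 11 for LPS over time. The deposited table gave 743 for Fc, 30 for LPS, 1 for avidin, 20 for LPS-avidin and 15 for LPS-Fc at 30 min, 77 for Fc, 17 for avidin, 3 for LPS-mannan, 76 for Fc-avidin and 32 for mannan-avidin at 60 min and 43 for Fc and 17 for mannan over time. The floored signal gave 34 for LPS, 3 for avidin, 14 for LPS-avidin, 10 for LPS-Fc and 0 (limma, 1917 unadjusted) for Fc-avidin at 30 min, 86 for Fc, 21 for avidin, 77 for Fc-avidin and 36 for mannan-avidin at 60 min and 45 for Fc and 17 for mannan over time. With no filter on dim probes there were 1 for avidin, 6 for LPS-avidin, 11 for LPS-Fc and 7 for mannan-avidin at 30 min, 19 for avidin at 60 min and 1 for avidin over time, with the strict filter 69 for avidin at 30 min, with all probes 2 for Fc-avidin at 30 min and with trend and robust 164 for avidin at 30 min. Without both later-processed arrays there were 1 for avidin and 2 for mannan-avidin at 30 min and 26 for LPS-mannan and 32 for Fc-mannan at 60 min, with contaminated spots missing 34 for avidin, 152 for LPS-mannan and 20 for Fc-mannan at 30 min and 123 for avidin, 210 for LPS-Fc, 62 for LPS-mannan and 124 for Fc-mannan at 60 min, and without the far end of the array 2 for mannan-avidin at 30 min, 17 for LPS-avidin and 5 for Fc-mannan at 60 min and 7 for mannan over time.

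Reversed values follow, those of Cdc23 with no measured size (below background in untreated cells). Without the slide series the interferon list for mannan at 30 min reversed in its test direction (median −0.017). Without the slide series, and then with it as a random block, Cdc23 was −0.018 and −0.029 for LPS, −0.16 and −0.17 for mannan, −0.097 and −0.11 for LPS-avidin, −0.24 and −0.25 for mannan-avidin at 60 min, −0.21 and −0.23 for LPS over time. Ak6 was 0.14 and 0.15 for LPS, 0.064 and 0.075 for mannan, 0.15 and 0.16 for LPS-avidin, 0.071 and 0.082 for mannan-avidin at 60 min. Wnt8a was 0.023 and 0.033 for mannan-avidin, −0.019 and −0.029 for Fc-mannan at 30 min, −0.033 and −0.048 for mannan over time. Dld was 0.013 and 0.031 for mannan-avidin at 60 min, 0.23 and 0.25 for LPS over time. With contaminated spots missing Cdc23 was −0.31 for Fc, −0.48 for LPS, −0.46 for mannan, −0.56 for LPS-avidin, −0.39 for Fc-avidin and −0.54 for mannan-avidin at 60 min and −0.53 for Fc and −0.88 for LPS over time. Wnt8a was 0.0097 for LPS-avidin, 0.0061 for LPS-Fc, 0.023 for mannan-avidin and −0.019 for Fc-mannan at 30 min and −0.20 for LPS and −0.12 for mannan over time.

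With the replicate number as a block beside the slide series the counts were 23 for LPS and 2 for mannan-avidin at 30 min and 17 for avidin, 18 for mannan, 3 for LPS-mannan and 5 for Fc-mannan at 60 min, and 39 gene calls and 3 list calls ended. The deviations of arrays with the same number correlated at −0.14 to 0.21. In 0 of 8 comparisons with untreated cells were all pairs above 0.1, which leaves a shared culture or day open. With each array left out in turn the counts ran from 671 to 1754 for Fc, 8 to 159 for LPS, 1 to 507 for avidin, 10 to 31 for mannan, 3 to 5 for LPS-avidin, 5 to 7 for LPS-Fc, 17 to 61 for LPS-mannan, 0 to 26 for Fc-avidin (0 in limma, 1780 to 2010 unadjusted), 2 to 25 for mannan-avidin and 3 to 31 for Fc-mannan at 30 min, 32 to 41 for Fc, 16 to 32 for LPS, 6 to 42 for avidin, 19 to 33 for mannan, 16 to 28 for LPS-avidin, 9 to 42 for LPS-Fc, 3 to 24 for LPS-mannan, 28 to 31 for Fc-avidin, 17 to 31 for mannan-avidin and 3 to 27 for Fc-mannan at 60 min and 12 to 20 for Fc, 14 to 20 for LPS, 0 to 1 for avidin (0 in limma, 900 to 1662 unadjusted), 10 to 25 for mannan and 6 to 37 for untreated over time. In these fits 303 of 1871 gene calls and 72 of 720 list calls ended, and 0 reversed. A lone array left in a group was assumed to vary like the others. Comparisons linked by LPS replicate 1 at 30 min or Fc replicate 3 at 60 min were not fitted without it. Lists were not tested with the random block or with trend and robust.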

Other observations

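Apart from the splits of untreated arrays and the lists for Fc beads, tests in this part were chosen after the results were seen. Untreated cells differed between 60 and 30 min in 12 probes, 4 higher and 8 lower. The transcription repressor Klf11 rose by 1.45 ± 0.18 (SE, adjusted p = 0.00055, n = 3 each, higher in 3 of 3 arrays), Frat2 by 1.22 ± 0.22 (adjusted p = 0.033) and the interferon-induced Ifitm1 by 1.05 ± 0.20 (adjusted p = 0.049). Id1, an inhibitor of differentiation, fell by 1.39 ± 0.21 (adjusted p = 0.0036) and the stress gene Gadd45g by 1.21 ± 0.18 (adjusted p = 0.0034). Klhl11 fell by 0.86 ± 0.16 and Jun by 0.73 ± 0.13 (adjusted p = 0.034 each). NF-kB targets had a median of 0.24 (adjusted p = 5.6e-08, and adjusted p = 0.012 with an estimated correlation), with 0 of 37 called in limma, 13 up and 1 down at an unadjusted p under 0.05 and 9 up adjusted over the list alone. Interferon genes had a median of −0.20 (adjusted p = 0.0024, but adjusted p = 0.14 with an estimated correlation and 0.79 without the slide series), with 0 of 28 called in limma or over the list alone and 3 down unadjusted. No slide series held both groups. Without the block 359 probes differed, 9 of them in both models, and Wnt8a moved from −1.82 to −0.06. Klf11, Id1 and Gadd45g held in all 11 reduced fits, none without LPS replicate 1 at 30 min. Frat2, Ifitm1, Klhl11 and Jun were kept in 5, 2, 5 and 3 (highest adjusted p = 0.081, 0.15, 0.087 and 0.10). The count was 6 without untreated replicate 2 at 30 min or replicate 1 or 3 at 60 min, and 37 and 20 without LPS replicates 2 and 3 at 30 min.

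Lists that shifted in none of the 8 comparisons of beads with untreated cells are given here for Fc beads at 30 min. In the NRF2 list of 17 tested genes Hmox1, which degrades heme, rose by 0.44 ± 0.11 (adjusted p = 0.016) and the glutathione reductase Gsr fell by 1.05 ± 0.19 (adjusted p = 0.0014), and the same 2 passed adjusted over the list alone. Its median and mean lay below 0 (−0.0059 and −0.022) against a test direction of up (adjusted p = 0.96). Of 24 glycolysis genes 0 passed in limma or adjusted over the list alone, with 1 up and 5 down at an unadjusted p under 0.05 (adjusted p = 0.62). Of 5 fibroblast markers 0 passed in limma, over the list alone or unadjusted (adjusted p = 0.93), and likewise 0 of 4 epithelial and erythroid markers (adjusted p = 0.86). Of 9 lymphocyte markers 0 passed in limma or over the list alone, with 1 up and 1 down unadjusted, a median of 0.018, a mean of −0.0072 and a test direction of down (adjusted p = 0.96). Of 8 granulocyte and dendritic markers 1 rose, or 2 adjusted over the list alone (adjusted p = 0.15).

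The 990 probes lower with Fc beads at 30 min averaged 8.89 ± 0.10 (SD, n = 3) there, 9.53 ± 0.12 in untreated cells and 9.14 ± 0.20, 9.15 ± 0.09 and 9.44 ± 0.09 with avidin, LPS and mannan beads. If they followed variation between arrays not tied to the groups, the first component of the replicate deviations of the 23 arrays of the 8 other groups would track the Fc change. Across genes, which are not independent replicates, r was 0.40, between the bounds set for and against it, and 94.2% of the lower genes loaded to 1 side against 46% of all genes. If the change belonged to Fc beads alone, their median difference from avidin would near that from untreated cells. The ratio was 0.43 (−0.24 against −0.55), but picking genes on these arrays can bias it either way, so it cannot decide. The shared series and small groups keep both explanations open.

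Tnf was higher but Egr2, Plk2 and Ccl3 were lower with LPS than with Fc beads at 60 min. The later processing day of 2 arrays is argued against as the whole cause, as 4 of 4 genes kept direction and call with the day as a block (1.12 for Tnf, −0.95 for Egr2, −0.98 for Plk2 and −0.67 for Ccl3). A response that differs with the coating may account for the pattern, as an untested hypothesis found on the same data. Other technical explanations stay open.

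The 6 arrays of a comparison have 10 splits, the real one included, too few for a share under 0.05. Against untreated cells the real count and the highest other were 1548 and 1 for Fc, 62 and 54 for LPS, 7 and 1 for avidin and 10 and 30 for mannan at 30 min, and 44 and 48 for Fc, 25 and 8 for LPS and 32 and 85 for avidin at 60 min. Splits with as many probes, the real one included, numbered 1, 1, 1, 2, 2, 1 and 2. Between beads at 30 min they were 3 and 217 for LPS against avidin, 6 and 489 for LPS against Fc, 54 and 16 for LPS against mannan, 1 and 62 for Fc against avidin, 4 and 2 for mannan against avidin and 6 and 3 for Fc against mannan (4, 4, 1, 4, 1 and 1 splits). At 60 min they were 26 and 5 for LPS against avidin, 34 and 26 for LPS against Fc and 35 and 290 for Fc against avidin (1, 1 and 3 splits), and for untreated cells over time 12 and 0 (1 split). The splits that put arrays of the same slide series together gave as many probes in 4 comparisons: those joining LPS replicate 1 with a pair of avidin or Fc arrays at 30 min, and those joining Fc replicates 1 and 2 with avidin replicate 1 or 2 or untreated replicate 3 at 60 min. The arrays of 1 shared series gave 2 probes for LPS against avidin, 3 for LPS against Fc, 21 for Fc against untreated cells and 22 for Fc against avidin. The splits with 30, 85, 217, 489, 62 and 290 probes called several times the real count and point to a structure of the arrays, in part beyond the slide series, since 85 and 62 came from arrays of 1 series.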
